A study of Mus musculus with 9 samples.

How the data were processed

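RNA sequencing libraries were available from 9 cultures of mouse pancreatic cancer cells. Per the labels, the cells were primary pancreatic cancer cells from mice with an activated Kras allele, floxed Trp53 and floxed Col1a1, recombined by a Cre driven from the Pdx1 promoter. They were grown in medium with low serum on plates coated with vehicle, with collagen I homotrimers or with collagen I heterotrimers. Each coating had 3 libraries. The series describes them as biological replicates, and the sample titles give each library the words cell line and a different number, without saying whether these were separate lines or separate platings. The numbers run in blocks by coating, so any processing order cannot be separated from the coating. The p-values therefore measure the spread between these samples, which may be partly technical. If the samples came from a single line, the p-values do not cover differences between lines.

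Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a stranded mRNA kit. The submitters' processing notes name STAR, HTSeq, DESeq2 and the mouse build mm10. Versions, the annotation and the strand setting are not given in the sources used here. The authors deposited a table of raw counts per gene symbol, with 18949 genes that had at least 1 count in some library. Total counts ran from 40578849 to 56894072 per library. A second deposited table holds normalised signal values. All 170541 of its values equalled the raw counts after multiplication by 1 size factor per library, with the largest relative deviation at 5.11e-15. Those factors equalled median-ratio size factors recomputed from the counts, with a largest difference of 2.22e-16. No columns of unmatched samples were present. Because counting by gene symbol can split reads between near-identical genes, values for Gsta1, the Ugt genes, Clca4, the prolactin family genes Prl2c2 and Prl2c3, histones, actins, ribosomal proteins and class I histocompatibility genes are uncertain as to the family member.

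The raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr with a minimum count of 10 were kept, which left 13184 genes and removed 5765. Libraries were scaled with TMM factors. All 9 libraries entered 1 model with a mean per coating, and the 3 comparisons were contrasts of a robust quasi-likelihood fit with 6 residual degrees of freedom. An F-test of any difference among the 3 coatings used the same fit. The p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Gene levels are CPM computed with the TMM-scaled library sizes, given as mean ± SD over 3 libraries. Fold changes are on the log2 scale, with the standard error derived from the F statistic. The common biological coefficient of variation was 0.0585. Depth limits low genes most, and a floor of 3 counts over a group was set for any fold.

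Gene lists, the genes to be named, the tests and most alternatives were fixed before the data were examined. There were 41 lists with 824 members, of which 785 were in the table and 668 were tested. Some genes were members of several lists, so the lists are not fully separate results. Lists with at least 5 tested members, 37 in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Its p-values were adjusted over all 111 list tests. Camera with an estimated correlation and fry were run beside it. Of the other 4 lists, the engineered genes had 4 tested members and are given singly, the acinar markers had 3, the islet markers had 2, and the mitochondrially encoded genes had 0.

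The named genes follow a rule. They are the engineered genes, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 8 CPM and no overlap between the groups, leaving out unnamed models and pseudogenes, and up to 4 members per list with the smallest unadjusted p. Gene positions come from GENCODE release M21, whose assembly corresponds to mm10, and were found for 284 of the 290 named genes.

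Replicate libraries were compared before averaging. The 9 pairs within a coating had a chi-square per degree of freedom of 6.81 to 19.96 over genes, so none agreed within sampling noise. The fold changes shared by both collagen comparisons were set beside 20 simulations of unchanged groups against the same vehicle libraries.

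The tests were tried on simulated counts drawn from the observed means and library sizes, with 200 changed genes per comparison. For homotrimer versus vehicle, on 13033 genes, 70.1% of genes changed by 0.5 on the log2 scale were recovered, 95.4% of those changed by 1 and 100% of those changed by 2. False calls made up 5.91% of the calls in that simulation. They made up 9.69% for heterotrimer versus vehicle, on 13055 genes, and 4.32% for homotrimer versus heterotrimer, on 13034 genes. The data had a far larger share of called genes, at 64.6%, 66.2% and 40.2% for the comparisons in that order. The shares recovered and falsely called may therefore differ in the data. Camera called 0 of 20 random lists in each of these 3 simulations. The simulated genes were drawn independently, so this cannot show how camera behaves on lists of correlated genes. In the data, the estimated correlation was 0.73 for the G2 and M phase genes and 0.914 for the cytosolic ribosomal proteins.

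Alternatives covered median-ratio size factors, library size alone, no count filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on the deposited normalised values with pseudocounts of 1 and 0.5, a fit of only the libraries compared, a fit without robust spread, and leaving out each library. A correction for GC content and transcript length, with both matched for 98.7% of genes, and a minimum mean of 8 CPM were added after seeing the data.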

Results

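The transcriptomes of mouse pancreatic cancer cells, labelled as carrying floxed Col1a1 with a Pdx1-driven Cre, were compared after growth on 3 coatings. The coatings were vehicle, collagen I homotrimers, which consist of the chain encoded by Col1a1 alone, and collagen I heterotrimers, which also contain the chain encoded by Col1a2. Each coating had 3 libraries, with 40578849 to 56894072 counts per library. Genes detected numbered 15546 to 15858 in the vehicle and homotrimer libraries and 16561 to 16918 in the heterotrimer libraries.

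The engineered genes were examined in every library. Col1a1 (chromosome 11, 94936224 to 94953042, mm10) was close to the detection limit, with 10 to 14 counts in each vehicle library, 77 to 80 in each homotrimer library and 26 to 36 in each heterotrimer library. Its mean level was 0.286 ± 0.0334 CPM on vehicle, 1.58 ± 0.192 CPM on homotrimers and 0.601 ± 0.0737 CPM on heterotrimers (SD, n = 3 each). Gene-level counts include exons outside the deleted parts, so Trp53 at 21.8 to 31.8 CPM and Kras at 65.3 to 84.9 CPM do not test the recombination, and neither do the counts of Col1a1. Pdx1, the pancreatic transcription factor whose promoter drives the Cre, rose from 16.8 ± 0.879 CPM on vehicle to 30.3 ± 2.37 on homotrimers and 31.1 ± 1.48 on heterotrimers (SD, n = 3 each).

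The first principal component of the tested genes held 59.9% of the variance and separated vehicle from both collagens. The second component held 23.2% and separated the 2 collagens. Correlations of log2 CPM were 0.99534 to 0.99637 within coatings and 0.96925 to 0.99114 between them. The F-test found a difference among the coatings for 10337 of 13184 genes (78.4%).

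**Figure D1:**
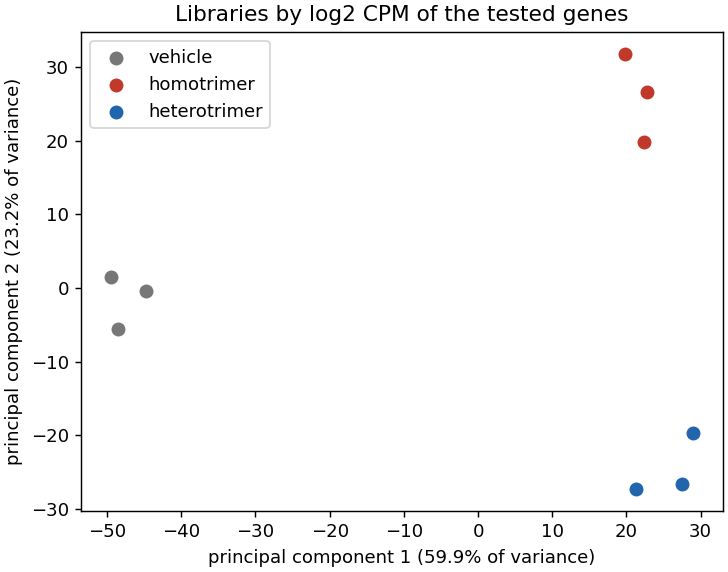
Each point is a library, placed by the first 2 principal components of log2 CPM, with the percent of variance on each axis and the coating by colour. The vehicle libraries lie between -49.53 and -44.76 on component 1, and the collagen libraries lie between 19.85 and 29.03.

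The first comparison asked how cells responded to collagen I homotrimers relative to vehicle. The largest rises included genes for chemokines and acute phase proteins. Lcn2, an iron-sequestering acute phase protein (chromosome 2, 32384633 to 32388252), rose from 0.0857 ± 0.0424 CPM to 184 ± 54.0 CPM (SD, n = 3), a log2 fold change of 11 ± 0.711 (SE), and had 11 counts over the vehicle libraries. Nos2, the inducible nitric oxide synthase, rose by 9.18 ± 0.311 (adjusted p = 7.71e-08). The chemokine genes Cxcl5, Ccl20, Cxcl3 and Cxcl1 rose by 4.80, 4.60, 4.03 and 3.00 on the log2 scale, and the complement gene C3, Clca4, Lbp and the adhesion receptor gene Vcam1 by 4.25, 3.94, 3.63 and 3.54. The largest falls included Xirp2, with log2 fold change -10.04 and 5 counts left over the homotrimer libraries, the collagenase gene Mmp13 at -5.66 ± 0.0877 and the transcription factor gene Klf2 at -5.19 ± 0.134. Stc1, Flrt3, Chac1, Pgf, Sprr1a, Trib3 and Mmp10 fell as well, with log2 fold changes from -3.56 to -2.73.

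Across all tested genes, edgeR's quasi-likelihood test called 8519 (64.6%), of which 4342 were higher and 4177 lower on homotrimers. At least 2-fold changes were found for 427 higher and 682 lower genes, of which 141 and 310 had a mean under 1 CPM. With only genes reaching 1 CPM in 3 libraries, 736 genes changed at least 2-fold in place of 1109.

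Among the NF-kB targets and cytokines, 25 of 29 tested genes rose and 3 fell, with a median log2 fold change of 1.12 and the same counts when adjusted over the list alone. Ccl2, a monocyte attractant, rose from 256 ± 15.7 CPM to 1772 ± 54.3 CPM, and Csf1, a macrophage growth factor gene, rose by 2.26 ± 0.0648. Camera called this list (adjusted p = 1.24e-07, and adjusted p = 0.298 with an estimated correlation). All 30 G2 and M phase genes rose, also when adjusted over the list alone, with a median of 0.77 and Ccnb2 at 1.33 and Plk1 at 1.04 (adjusted p = 1.92e-11, and adjusted p = 0.443 with an estimated correlation). Of 28 G1 to S phase genes, 24 rose and 0 fell, or 25 and 0 adjusted over the list alone, with Rrm2 at 1.09 and Mcm5 at 0.84 (adjusted p = 1.42e-06, and adjusted p = 0.545 with an estimated correlation). Among SRF and MRTF targets, which encode much of the actin cytoskeleton, 13 of 15 rose and 1 fell by either adjustment, including Actg1 at 0.89 and Tagln2 at 1.31 (adjusted p = 0.000139, and adjusted p = 0.331 with an estimated correlation). The MYC targets had 20 of 26 higher and 2 lower by either adjustment (adjusted p = 0.00288, and adjusted p = 0.667 with an estimated correlation).

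Amino acid and lipid genes moved the other way. All 22 tested ATF4 and amino acid response genes fell, also when adjusted over the list alone, with a median of -1.08. Chac1, a glutathione-degrading enzyme gene, fell from 135 ± 6.36 CPM to 12.6 ± 0.570 CPM, and Asns, the asparagine synthetase gene, had a log2 fold change of -1.83 (adjusted p = 4.08e-11 for the list, and adjusted p = 0.272 with an estimated correlation). Of 24 cholesterol and sterol synthesis genes, 23 fell and 0 rose by either adjustment, with Lss at -1.31 and Insig1 at -1.31 (adjusted p = 2.26e-10, and adjusted p = 0.331 with an estimated correlation). In the glycolysis list 15 of 18 genes fell and 0 rose by either adjustment, with Aldoa at -0.85 (adjusted p = 4.22e-05, and adjusted p = 0.443 with an estimated correlation). In the hypoxia response 14 of 18 fell and 3 rose by either adjustment, with Vegfa at -1.23 and Bnip3 at -1.43 (adjusted p = 0.000434, and adjusted p = 0.443 with an estimated correlation). The PI3K and FOXO targets had 13 of 18 lower and 3 higher by either adjustment, with Klf4 at -2.34 (adjusted p = 0.013, and adjusted p = 0.519 with an estimated correlation). The fatty acid synthesis genes had 10 of 14 lower and 1 higher by either adjustment, with Scd1 at -0.81 (adjusted p = 0.00644, and adjusted p = 0.519 with an estimated correlation).

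The calls of 4 further lists also ended under another alternative than the estimated correlation. The YAP and TEAD targets had 12 of 22 higher and 4 lower, or 13 and 4 adjusted over the list alone (adjusted p = 0.0345, adjusted p = 0.5 with an estimated correlation, and 0.0643 without homotrimer library 2). The cytosolic ribosomal proteins had 12 of 30 higher and 0 lower, or 11 and 0 adjusted over the list alone (adjusted p = 0.0191, adjusted p = 0.767 with an estimated correlation). That call ended without vehicle library 2 (0.0578), without homotrimer library 1 (0.0668) and after GC and length correction (0.763). In the NRF2 and oxidative stress list 15 of 23 rose and 4 fell by either adjustment, with Gsta4 at 1.23 but Hmox1 at -1.58 (adjusted p = 0.0228, adjusted p = 0.387 with an estimated correlation, and 0.062 after GC and length correction). The basal pancreatic cancer genes had 5 of 7 lower and 0 higher by either adjustment, with Lamc2 at -1.91 (adjusted p = 0.0311, adjusted p = 0.443 with an estimated correlation, and 0.0532 without homotrimer library 3).

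The second comparison asked the same of heterotrimers relative to vehicle. Lcn2 rose to 109 ± 36.3 CPM (SD, n = 3; log2 fold change 10.24 ± 0.732), Nos2 by 9.20 ± 0.31, Ccl20 by 5.79 ± 0.176 and Cxcl5 by 4.70 ± 0.101. Gsta1, a glutathione transferase gene (chromosome 9, 78230656 to 78242684), rose from 0.545 ± 0.136 to 21.1 ± 2.40 CPM, and Aldh3a1, an aldehyde dehydrogenase gene, rose from 2.66 ± 0.198 to 96.4 ± 8.56 CPM (SD, n = 3 each). Both were also higher on homotrimers than on vehicle, at 2.16 and 14.5 CPM. The glucuronosyltransferase genes Ugt1a6a and Ugt2b34 rose by 4.86 and 4.33 on the log2 scale, C3 by 4.35 and Clca4 by 4.26. Xirp2, Klf2 and Mmp13 had log2 fold changes of -8.50, -4.60 and -4.16, and Pgf, Sprr1a, Rhob, Cdh16, Tnc, Atf3 and Csrnp1 fell with values from -3.69 to -2.38.

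Of the tested genes, 8722 (66.2%) were called by edgeR's quasi-likelihood test, 4411 higher and 4311 lower on heterotrimers. At least 2-fold changes were found for 761 higher and 398 lower genes, of which 346 and 136 had a mean under 1 CPM, and for 198 higher and 167 lower genes at a mean of at least 8 CPM. With only genes reaching 1 CPM in 3 libraries, 749 genes changed at least 2-fold in place of 1159.

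All 30 G2 and M phase genes rose, also when adjusted over the list alone, with Ccnb2 at 1.35 (adjusted p = 1.92e-11, and adjusted p = 0.443 with an estimated correlation). The G1 to S phase genes had 22 of 28 higher and 2 lower by either adjustment, with Rrm2 at 1.16 (adjusted p = 0.000119, and adjusted p = 0.636 with an estimated correlation). Among NF-kB targets and cytokines 21 of 29 rose and 5 fell by either adjustment, with Cxcl3 at 3.89 and Ccl2 at 2.15 (adjusted p = 1.64e-05, and adjusted p = 0.331 with an estimated correlation). Of 23 NRF2 and oxidative stress genes, 18 rose and 2 fell, or 19 and 2 adjusted over the list alone, with the glutathione synthesis gene Gclc at 1.54 and the ferritin gene Fth1 at 1.22 (adjusted p = 7.16e-06, and adjusted p = 0.272 with an estimated correlation). Of 21 interferon-stimulated genes, 11 rose and 2 fell by either adjustment, with Xaf1 at 1.72 and Stat1 at 0.74 (adjusted p = 0.0209, and adjusted p = 0.443 with an estimated correlation).

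Lower lists were the ATF4 and amino acid response, with 17 of 22 lower and 2 higher by either adjustment and Chac1 at -2.31 (adjusted p = 3.66e-05, and adjusted p = 0.422 with an estimated correlation). Cholesterol and sterol synthesis had 20 of 24 lower and 2 higher by either adjustment, with Ldlr at -0.97 (adjusted p = 2.57e-06, and adjusted p = 0.443 with an estimated correlation). Glycolysis had 14 of 18 lower and 0 higher by either adjustment, with Pfkl at -0.85 (adjusted p = 0.000337, and adjusted p = 0.443 with an estimated correlation). The hypoxia response had 14 of 18 lower and 3 higher by either adjustment, with Bnip3 at -1.47 but Angptl4 at 2.56 (adjusted p = 0.00059, and adjusted p = 0.443 with an estimated correlation). ERK pathway output had 17 of 23 lower and 2 higher by either adjustment, with Dusp4 at -1.61 and Egr1 at -1.80 (adjusted p = 0.000356, and adjusted p = 0.387 with an estimated correlation). Close to the threshold but not called were the PI3K and FOXO targets, with 9 of 18 lower and 2 higher (camera adjusted p = 0.0509). The same held for the SRF and MRTF targets, with 10 of 15 higher and 3 lower (camera adjusted p = 0.0509).

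The 2 sets of fold changes against vehicle shared a Pearson r of 0.7713 across genes, which are not independent replicates. Unchanged groups simulated against the same vehicle libraries gave a mean r of 0.534 and at most 0.571. The covariance was 0.402 against a simulated 0.0175, a difference of 0.385. Called genes were higher on both collagens in 3338 cases and lower on both in 3208, where independent lists would give 1453 and 1366. The simulations gave at most 0 and 2, but they held no changed genes, so hardly any calls were possible. They cannot show how much overlap the shared vehicle libraries add. The vehicle libraries are too few to split, so part of the excess overlap may come from the shared controls.

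**Figure D2:**
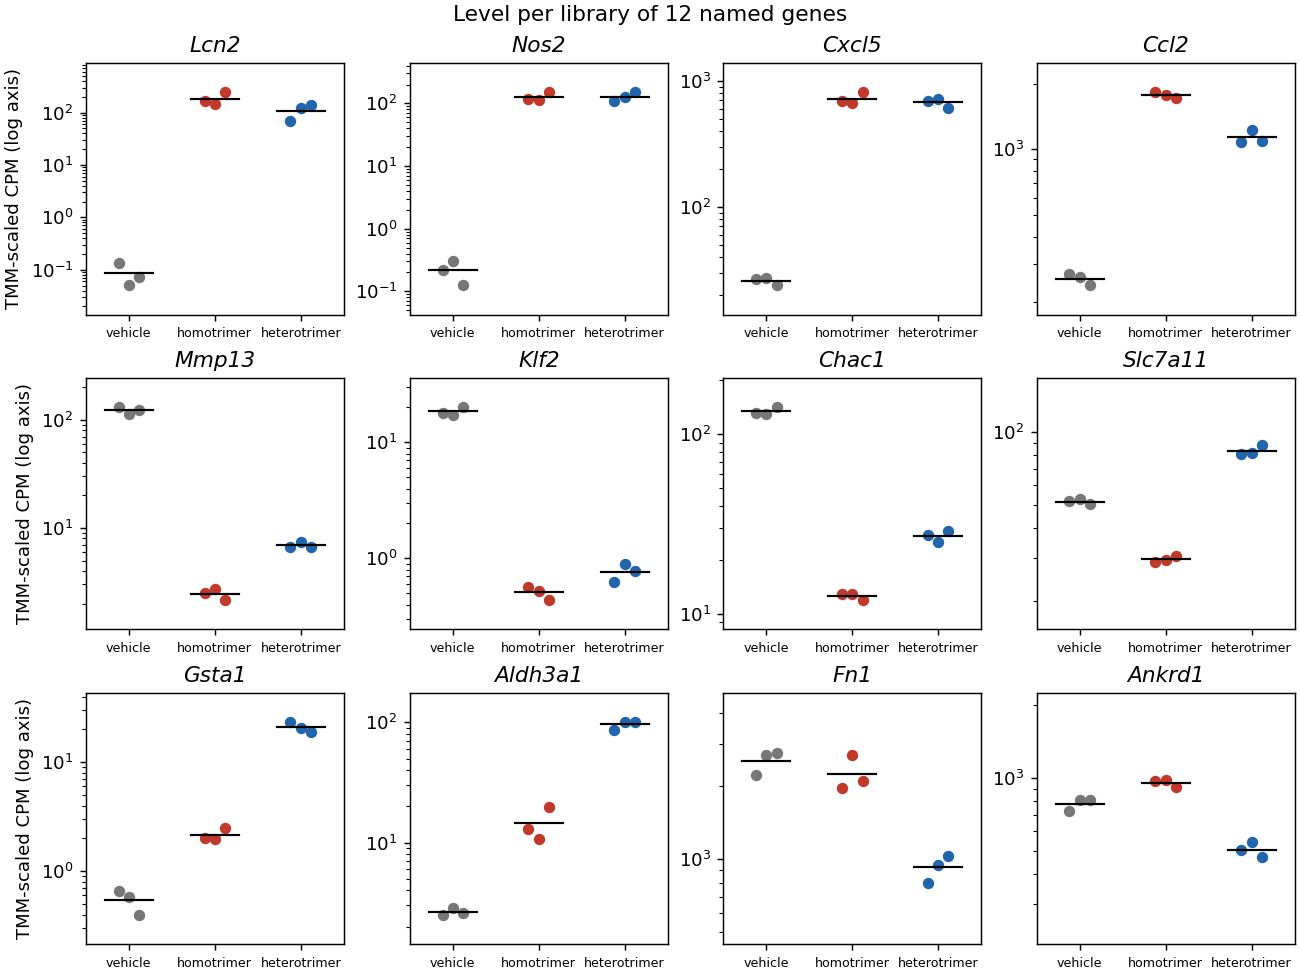
Each panel shows the TMM-scaled CPM of a named gene on a log axis, with a point per library, a line at the mean of 3 libraries and colours for the coatings. Lcn2, Nos2, Cxcl5 and Ccl2 lie higher on both collagens, Mmp13, Klf2 and Chac1 lie lower on both, and Slc7a11 averages 51.5 CPM on vehicle, 29.8 on homotrimers and 83.3 on heterotrimers.

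The third comparison set homotrimers directly against heterotrimers, which is also the test of whether the responses to the 2 collagens differ. Fn1, the fibronectin gene, was at 2252 ± 382 CPM on homotrimers and 925 ± 120 CPM on heterotrimers (SD, n = 3 each), a log2 fold change of 1.28 ± 0.143, while vehicle was at 2547 ± 287 CPM. Il1rl1, an interleukin receptor gene, Col12a1, Pdgfb, Mcam and Adamts7 were higher by 1.92, 1.47, 1.38, 1.37 and 1.33 on the log2 scale, and Ccbe1, Edn1, Ctgf and Angptl2 by 1.32, 1.27, 1.17 and 1.12. Among the genes furthest in the other direction were Ugt2b34 at -3.28, Gsta1 at -3.28, Tmigd1 at -2.99, Aldh3a1 at -2.73, Lgals4 at -2.53, Vnn1 at -2.49, Acot2 at -2.26 and Mep1a at -2.12. The prolactin family genes Prl2c3 and Prl2c2 were at -2.12 and -2.11.

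Of the tested genes, 5296 (40.2%) were called by edgeR's quasi-likelihood test, 2689 higher and 2607 lower on homotrimers, with a median absolute log2 fold change of 0.31. Only 40 genes were at least 2-fold higher on homotrimers, against 574 at least 2-fold lower. Of those 574, 371 had a mean under 1 CPM over all libraries, and genes under 1 CPM had a median log2 fold change of -0.46, against 0.021 for the rest. Relative to vehicle, genes under 1 CPM had medians of -0.22 on homotrimers and 0.17 on heterotrimers. After thinning to 40578849 counts each, heterotrimer libraries detected 16407 to 16492 genes, vehicle libraries 15591 to 15724 and homotrimer libraries 15393 to 15534. At least 2-fold changes numbered 285 when genes had to reach 1 CPM in 3 libraries and 84, with 12 higher and 72 lower, at a mean of at least 8 CPM.

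**Figure D3:**
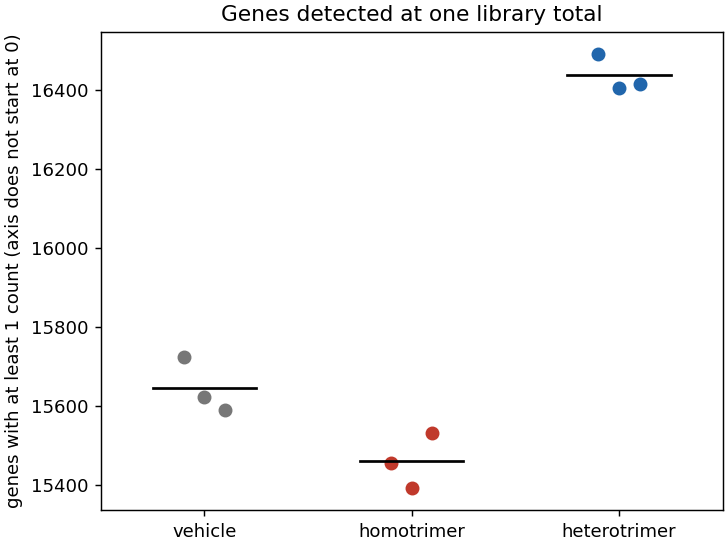
Points are libraries thinned to the same total of 40578849 counts, grouped by coating, with the number of genes holding at least 1 count on an axis that does not start at 0 and lines at the means. The heterotrimer libraries lie between 16407 and 16492, above the vehicle libraries at 15591 to 15724 and the homotrimer libraries at 15393 to 15534.

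Cytoskeletal and adhesion lists were higher on homotrimers. Of 22 YAP and TEAD targets, 17 were higher and 0 lower by either adjustment, with Ankrd1 at 0.92 and Cyr61 at 0.87 (adjusted p = 9.47e-07, and adjusted p = 0.272 with an estimated correlation). Of 15 SRF and MRTF targets, 13 were higher and 1 lower by either adjustment, with Tpm1 at 0.48 (adjusted p = 2.94e-05, and adjusted p = 0.298 with an estimated correlation). Of 26 focal adhesion and integrin signalling genes, 18 were higher and 2 lower, or 18 and 4 adjusted over the list alone, with Zyx at 0.56 and Bcar1 at 0.48 (adjusted p = 0.000146, and adjusted p = 0.387 with an estimated correlation). Mesenchymal genes had 8 of 13 higher and 2 lower, or 9 and 2 adjusted over the list alone, with Cdh2 at 0.42 and Zeb2 at 0.46 (adjusted p = 0.0202, and adjusted p = 0.298 with an estimated correlation). TGF-beta targets had 10 of 18 higher and 3 lower, or 11 and 4 adjusted over the list alone, with Pmepa1 at 0.69 (adjusted p = 0.00791, and adjusted p = 0.443 with an estimated correlation). ERK pathway output had 12 of 23 higher and 1 lower, or 13 and 2 adjusted over the list alone, with Etv4 at 0.64 (adjusted p = 0.00545, and adjusted p = 0.443 with an estimated correlation). On homotrimers relative to vehicle, however, 14 ERK output genes fell and 4 rose by either adjustment, without a camera call (adjusted p = 0.0509). The MYC targets had 11 of 26 higher and 0 lower by either adjustment, with Myc at 0.55 (adjusted p = 0.00167, adjusted p = 0.667 with an estimated correlation, and 0.0762 by fry). NF-kB targets and cytokines had 14 of 29 higher and 6 lower by either adjustment, with Csf1 at 0.72 but Il33 at -1.64 (adjusted p = 0.0183, and adjusted p = 0.519 with an estimated correlation).

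For fibrillar collagens and matrix proteins, 8 of 14 were higher and 2 lower by either adjustment, with Tnc at 1.11, Col5a1 at 0.79 and Thbs1 at 0.71 (adjusted p = 0.0389, and adjusted p = 0.443 with an estimated correlation). This call ended when any vehicle library, any homotrimer library or heterotrimer library 2 was left out, with adjusted p-values of 0.0734 to 0.16. The basement membrane list had 5 of 14 higher and 5 lower, or 6 and 5 adjusted over the list alone, and was not called (adjusted p = 0.579). The G1 to S phase genes had 8 of 28 higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.0342, and adjusted p = 0.767 with an estimated correlation). That call ended without homotrimer library 1 (0.0698), homotrimer library 2 (0.11) or heterotrimer library 3 (0.426), and among genes reaching 1 CPM in 3 libraries (0.0679). The G2 and M phase genes had 1 of 30 higher and 3 lower, or 0 and 0 adjusted over the list alone, and were not called (adjusted p = 0.682).

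Epithelial, stress and antigen presentation lists were lower on homotrimers. All of these stand beside the wider detection of low-abundance genes in the heterotrimer libraries, and the narrower detection in the homotrimer libraries, given above. Of 22 ATF4 and amino acid response genes, 18 were lower and 0 higher, or 19 and 0 adjusted over the list alone, with the cystine transporter gene Slc7a11 at -1.49 ± 0.0496 (adjusted p = 3.81e-11, and adjusted p = 0.272 with an estimated correlation). Slc7a11 is also in the NRF2 list. It rose by 0.694 on heterotrimers relative to vehicle, where 17 of the 22 ATF4 genes fell and 2 rose. Of 23 NRF2 and oxidative stress genes, 18 were lower and 2 higher by either adjustment, with Hmox1 at -1.45 and Gclc at -1.06 (adjusted p = 4.93e-09, and adjusted p = 0.213 with an estimated correlation). Cholesterol and sterol synthesis had 17 of 24 lower and 2 higher, or 18 and 2 adjusted over the list alone, with Tm7sf2 at -0.90 (adjusted p = 2.5e-05, and adjusted p = 0.443 with an estimated correlation). Of 16 epithelial genes, 8 were lower and 2 higher, or 10 and 2 adjusted over the list alone, with the E-cadherin gene Cdh1 at -1.33 and Krt19 at -0.56 (adjusted p = 0.00723, and adjusted p = 0.272 with an estimated correlation). Classical pancreatic cancer genes had 9 of 16 lower and 2 higher by either adjustment, with Hnf4a at -0.74 and Foxa2 at -0.57 (adjusted p = 0.00756, and adjusted p = 0.443 with an estimated correlation).

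Of 21 interferon-stimulated genes, 14 were lower and 0 higher, or 16 and 1 adjusted over the list alone, with Xaf1 at -0.75 and Isg15 at -1.49 (adjusted p = 9.03e-05, and adjusted p = 0.298 with an estimated correlation). The class I histocompatibility and antigen processing genes had 7 of 12 lower and 1 higher, or 8 and 1 adjusted over the list alone, with H2-K1 at -0.56 (adjusted p = 0.0202, and adjusted p = 0.298 with an estimated correlation). Of 20 p53 targets, 9 were lower and 1 higher by either adjustment, with Perp at -1.47 (adjusted p = 0.0303, and adjusted p = 0.298 with an estimated correlation), in cells whose Trp53 was floxed. Beside these lists, the leukocyte markers Ptprc, Csf1r and Cd74 were lower on homotrimers than on heterotrimers at -1.83, -1.17 and -1.11, and their list of 6 had 0 higher and 3 lower by either adjustment without being called (adjusted p = 0.149). The Csf1r call ended without homotrimer library 2 (0.0855), heterotrimer library 1 (0.0899) or heterotrimer library 3 (0.0701). Of 10 replication-dependent histones, 8 were lower and 0 higher by either adjustment, with Hist1h1c at -1.67 and Hist1h2bc at -1.73 (adjusted p = 6.54e-05, and adjusted p = 0.272 with an estimated correlation). Most histone transcripts lack a poly(A) tail, and Rn45s, a ribosomal RNA precursor without one, held 0.416 to 0.427% of the counts on homotrimers and 0.499 to 0.614% on heterotrimers, against 0.357 to 0.579% on vehicle. Rn45s did not pass the test between the collagens (log2 fold change -0.39, adjusted p = 0.0987). The non-coding RNA list kept as a sign of RNA quality had 1 of 8 higher and 0 lower, or 0 and 0 adjusted over the list alone, and was not called (adjusted p = 0.678).

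**Figure D4:**
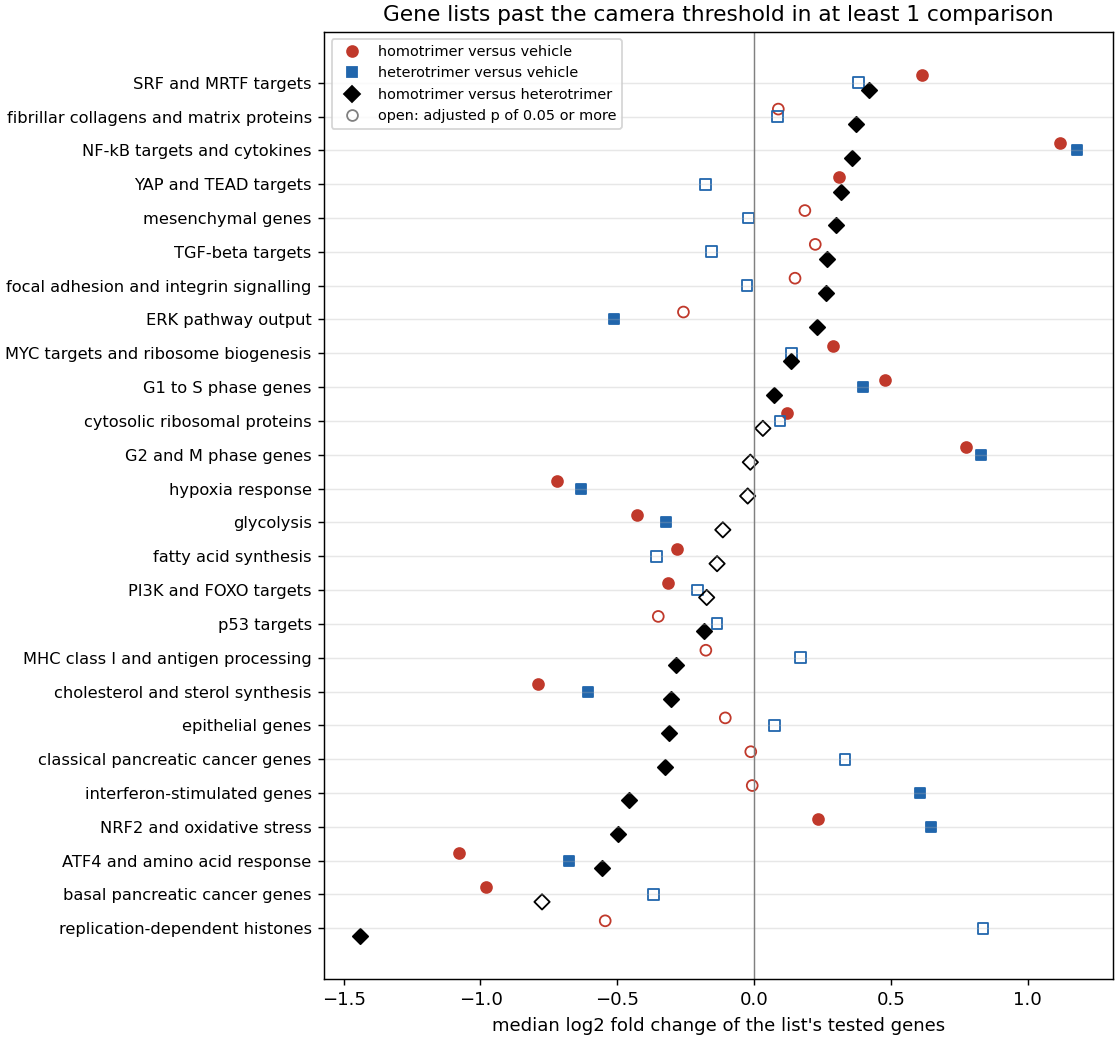
Points give the median log2 fold change of the tested genes of each list called by camera in at least 1 comparison, with shapes and colours for the 3 comparisons and filled points for adjusted p under 0.05. The NF-kB list has medians of 1.12 and 1.18 against vehicle, and the ATF4 list has medians of -1.08, -0.68 and -0.56 in the 3 comparisons.

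The tested lists of leukocyte, fibroblast and endothelial markers were not called. Csf1r, a macrophage receptor gene, had log2 fold changes of -4.01 on homotrimers and -2.85 on heterotrimers relative to vehicle. The macrophage and leukocyte list had 2 of 6 genes higher and 3 lower on homotrimers, and 4 higher and 2 lower on heterotrimers, relative to vehicle by either adjustment. Of 7 endothelial markers, 0 were higher and 2 lower on homotrimers than on heterotrimers, or 0 and 3 adjusted over the list alone, with Vwf at -3.05. Relative to vehicle, 2 were higher and 4 lower on homotrimers, and 4 higher and 1 lower on heterotrimers. Of 7 fibroblast markers, 2 were higher and 1 lower on homotrimers, and 2 higher and 0 lower on heterotrimers, relative to vehicle. Between the collagens, 2 fibroblast markers were higher and 3 lower on homotrimers. Fibroblast and endothelial marker lists were not called by camera in any comparison, with adjusted p-values from 0.315 to 0.748. The collagen receptors were not called by camera against vehicle or between collagens, with adjusted p-values of 0.837, 0.517 and 0.544, although Ddr2 was at 0.96 on heterotrimers relative to vehicle and Itga3 was at -0.35 and -0.94 on homotrimers and heterotrimers. Of 12 receptors, 4 rose and 5 fell on homotrimers, and 4 rose and 6 fell on heterotrimers, relative to vehicle. Camera tests for a shared direction, so opposite changes within a list offset each other.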

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

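The tests of the technical explanations below were chosen after the patterns were seen. The regroupings of libraries were fixed before their outcome was seen.

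Some named genes moved in opposite directions on the 2 collagens relative to vehicle and differed between the collagens by at least 2-fold in edgeR's quasi-likelihood test. They were found among 211 genes with opposite calls. Higher on homotrimers and lower on heterotrimers were Col12a1, Mcam and Adamts7, with log2 fold changes between the collagens of 1.47, 1.37 and 1.33. Lower on homotrimers and higher on heterotrimers were Anxa10 at -3.44, Vwf at -3.05, Acot2 at -2.26, Mep1a at -2.12, Hist1h2bc at -1.73, Hist1h1c at -1.67, Slc7a11 at -1.49, Ddr2 at -1.29 and Cd74 at -1.11. Vwf was low, at 0.201 CPM on vehicle, 0.0483 on homotrimers and 0.458 on heterotrimers, and its call against vehicle ended without vehicle library 2 on homotrimers (adjusted p = 0.0591) and without vehicle library 1 on heterotrimers (0.0609). The heterotrimer call also ended with DESeq2 (0.059) and on the deposited normalised values with pseudocounts of 1 (0.0794) and 0.5 (0.143).

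The first pattern is the inflammatory gene rise on both collagens. Leukocytes in the collagen wells would bring their abundant transcripts. Of Ptprc, Lyz2, Laptm5, Fcer1g, Csf1r and Cd74, which are not all in the tested leukocyte list, 0 had higher mean CPM on homotrimers than on vehicle. The 4 that were higher on heterotrimers added 1.02 CPM, which is 0.43% of the summed rise of Lcn2 and Nos2. These 6 genes were chosen after the data were seen and leave out both tested leukocyte markers that rose on homotrimers. The values show only that these 6 transcripts added little, and leukocytes are not excluded. The leukocyte list fixed beforehand was mixed and not called against vehicle. It had 2 of 6 genes higher and 3 lower on homotrimers, and 4 higher and 2 lower on heterotrimers. A substance in the coating other than collagen, such as a bacterial product, cannot be told apart from collagen because no coating control beyond vehicle was present. The interferon-stimulated genes, which a bacterial product could raise, had a median log2 fold change of -0.00647 on homotrimers and 0.607 on heterotrimers (adjusted p = 0.0209, and adjusted p = 0.443 with an estimated correlation), which does not decide it. A response to collagen itself remains a hypothesis.

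The second pattern is the wider detection of low-abundance genes on heterotrimers. After thinning, the homotrimer libraries in turn detected fewer genes than the vehicle libraries, at 15393 to 15534 against 15591 to 15724. Sequencing depth is argued against by thinning, after which the lowest heterotrimer library still detected 683 more genes than the highest other library. Genomic DNA would add similar counts per kb to all silent genes. Among coding genes with at most 2 counts over the vehicle libraries, the heterotrimer excess over homotrimers was compared per kb. In olfactory and vomeronasal receptor genes it was 0.0808 of that in other genes (0.0286 against 0.354 counts per kb). By this measure DNA may supply at most a small part of the excess counts. The pattern concerns genes detected, which the ratio of counts does not measure. The lengths came from the longest GENCODE transcript, and the annotation used for counting is not given, so the ratio is uncertain. Total counts rose from 65 on homotrimers to 208 on heterotrimers in the receptor genes, and from 4007 to 9380 in the others. Genes with a count rose from 43 to 124 of 1388 receptor genes and from 1278 to 2207 of 5682 others. How many of the added genes DNA accounts for was not tested. A wider low-level transcription, untested batch differences and RNA from other cells stay open.

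The third pattern is the fall of the ATF4, sterol and glycolysis lists and the rise of the mitotic list on both collagens. After GC and length correction the highest of the 8 adjusted camera p-values was 0.000262, which argues against GC content and length as the whole cause. With library size alone it was 0.000163. Camera compares a list with the other genes, and rescaling moves all genes of a library alike. That value could therefore hardly change and decides nothing about the scaling. Both values rest on the preset correlation, and all 8 calls were lost with an estimated correlation (adjusted p = 0.272 to 0.443). Cell density, attachment and medium depletion at harvest are not given in the sources used here. A growth difference that follows them may account for the pattern as well as a response to collagen.

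Regrouping the libraries bears on whether random assignment of single libraries could give as many genes. For the F-test among the coatings, 1 of 100 drawn splits, the real one, reached 10337 genes, and the highest other split gave 6268. That argues against random assignment of single libraries. The sample numbers run in blocks by coating, so a difference between blocks would give the same result and is not excluded. For the pairwise comparisons, 10 splits cannot give a share under 0.05. The real split was 1 of 10 in each, with 8519, 8722 and 5296 genes, and the highest other split gave 0.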

How the results depend on the processing

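The GC and length correction and the minimum mean of 8 CPM were chosen after seeing the data. The counts of changed genes stayed within 1.5 times the values above under the alternatives run, with leave-one-out ranges of 7814 to 8772 for homotrimer versus vehicle, 8037 to 8902 for heterotrimer versus vehicle and 4175 to 5276 between the collagens. Counts of genes changed at least 2-fold depended on the filter, because fewer low genes were tested. They were 736, 749 and 285 with 1 CPM in 3 libraries, and 373, 365 and 84 with a mean of at least 8 CPM, in the order of the comparisons above. With library size alone, the share of called genes that were higher was 55%, 58.4% and 41.9%, against 51%, 50.6% and 50.8%. Camera called 0, 0 and 0 lists with an estimated correlation, against 15, 10 and 19, and fry, which tests another hypothesis, called 33, 29 and 25. Among lists called by camera, fry did not call the cytosolic ribosomal proteins on homotrimers relative to vehicle (adjusted p = 0.0556). Between the collagens it did not call the MYC targets (0.0762) or the G1 to S phase genes (0.197). The correlation of fold changes was 0.8114 with 1 CPM in 3 libraries and 0.8705 with a mean of at least 8 CPM. Leaving out a library gave 0.7222 to 0.7957. The log2 fold change of Kcnq1ot1 on heterotrimers relative to vehicle was 0.1278 after GC and length correction, against -0.32, and the cause was not tested. That call also ended with library size alone (0.0601), with no count filter (0.0673) and in 5 leave-one-out fits (0.0517 to 0.0763). Among results for single named genes, 79 lost and 38 gained a call, 1 reversed and 9932 kept their side of the threshold. Among the 9932, genes without a call in either setting may have changed direction. No paired analysis was possible because the labels give no replicate numbers shared between coatings. Depth limits genes near the floor, such as Col1a1 and the leukocyte markers.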

Other observations

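Further gene groups, put together after the data were seen and so not independent evidence, are given as counts. Of 15 tested xenobiotic metabolism genes, 11 rose and 1 fell on homotrimers relative to vehicle, 14 rose and 1 fell on heterotrimers, and 13 were lower and 0 higher on homotrimers than on heterotrimers, with median log2 fold changes of 1.23, 2.53 and -1.22. Among 16 PPAR targets, 14 were lower and 1 higher on homotrimers than on heterotrimers, with a median of -0.65. Relative to vehicle, 8 rose and 4 fell on homotrimers, and 12 rose and 2 fell on heterotrimers, with medians of 0.292 and 1.03. Of 9 intestinal epithelial genes, 8 were lower and 0 higher on homotrimers than on heterotrimers, with a median of -1.11. Relative to vehicle, 2 rose and 3 fell on homotrimers, and 7 rose and 1 fell on heterotrimers, with medians of -0.264 and 1.2. These are counts of edgeR calls, and the groups were not tested as sets.

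Circadian clock genes were mostly lower on collagen, with 12 of 17 lower and 0 higher on homotrimers and 12 lower and 3 higher on heterotrimers, relative to vehicle, and 7 lower and 1 higher on homotrimers than on heterotrimers. Of 8 acute phase genes, 6 rose and 1 fell on homotrimers, and 6 rose and 2 fell on heterotrimers, with 1 higher and 1 lower on homotrimers than on heterotrimers. Of 7 complement genes, 4 rose and 0 fell on homotrimers, and 4 rose and 1 fell on heterotrimers, with 0 higher and 1 lower on homotrimers than on heterotrimers.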
